A study of Mus musculus with 20 samples.

How the data were processed

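Total RNA of LSECs was isolated with Trizol and sequenced as paired-end libraries on an Illumina HiSeq instrument, per the labels, in 20 samples of male mice. The labels name no gate used to isolate the cells other than c-Kit. The submitters' processing notes name bcl2fastq, TopHat2 2.0.13 and the mm10 genome build. The tool that counted reads per gene is not given in the sources used here. The deposited tables of the sorted cells and of the knockout experiment hold expected counts, also called estimated counts, per gene, 91.19% and 93.95% of them whole numbers. The deposited table of the MCD experiment holds whole-number counts per gene. Per the file headers, that table also holds the log2 ratio of the authors' own comparison and its adjusted p-value (FDR), for which the test is not given in the sources used here. Normalized values in the same tables were not used here. The 3 experiments were never pooled.

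Expected counts were rounded to whole numbers. The tables held 22322, 22298 and 22274 genes, of which 22267, 22255 and 22219 were found in GENCODE M21 by Ensembl ID. Symbols were taken by ID from that annotation, because in the MCD table only 68.5% of the table's own symbols equalled those of the annotation (97.1% and 98.1% in the other tables). An ID missing from the annotation kept the symbol that the other tables give it. The build of this annotation, GRCm38, may differ in gene models from the one used for counting.

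Groups followed the labels. Each experiment was fitted alone, with the genes kept by filterByExpr (minimum count 10) and TMM scaling, by the edgeR 4.0.16 quasi-likelihood method (glmQLFit with robust estimation, glmQLFTest, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The genes kept held 99.95%, 99.94% and 99.95% of the counts. CPM values use the TMM library sizes. Gene lists, 38 in all, were tested with camera of limma 3.58.1 on voom values (preset correlation 0.01, at least 3 members), adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run as alternatives. Camera with the preset correlation called 13, 16 and 10 lists in the sorted cells, the knockout and the MCD experiment, and with an estimated correlation it called 0 in each. The lists, the tests, the rule for named genes and the alternatives first listed below were fixed before the data were examined.

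The rule for named genes took Kit, then up to 10 higher and 10 lower genes with the largest change among those past the threshold, without overlap between the groups, with a mean of at least 5 CPM in the higher group and with a symbol that is not a predicted gene. From each list it took up to 4 members past the threshold. Where no member passed, at most 2 members were named, and only where camera called the list. Where under 5 genes passed, the 5 with the smallest p were given as values. The text prints a part of these genes, and some single-gene results are not reported here. Of the named genes that passed, 100 of 125 in the sorted cells and 10 of 28 in the knockout experiment passed in every fit that left out 1 library; those lost are given with their values where they are printed. A fold against a group at 0 counts was computed with a floor of 3 counts over the group, and a ratio against 1 to 3 counts has its exact Clopper-Pearson interval at a level of 0.95. Floors and intervals cover counting error only.

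Genes past the threshold with a log2 fold change of at least 1 in the sorted cells were carried into the other experiments as 2 sets, of 262 higher genes without Kit and 1578 lower genes. These were tested with camera and with an exact permutation test of a mean score per library (two-sided). Replicate numbers were checked as pairs. In the sorted cells the deviations of same-numbered libraries from their group means correlated across genes at 0.462, 0.349 and 0.379, against -0.352 to -0.055 for other pairs. In the knockout experiment 2 such pairs gave 0.145 and 0.341, against -0.34 to 0.334 for other pairs, which leaves a pairing open. In the MCD experiment 2 pairs gave -0.058 and -0.112, against -0.42 to 0.468 for other pairs, so its values show no pairing. No label states a pairing, so no block was used except as an alternative. No pair of libraries in a group was a copy, with a chi-square per degree of freedom of at least 9.88. The scaling moved the median of all genes by at most 0.011 in size between TMM and DESeq2 size factors.

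The alternatives fixed in advance were DESeq2 size factors in edgeR, DESeq2 1.42.0, no filter, a stricter filter, the replicate number as a block, a fold minimum, the 200 top genes as sets, sets without the lists of other cell types, and each library left out in turn. The stricter filter kept genes with at least 5 CPM in as many libraries as the smaller group holds. Others were chosen after seeing the data: the newer quasi-likelihood method of edgeR, a hepatocyte score as a covariate in the knockout experiment, a monocyte and neutrophil score as a covariate in the MCD experiment, every member in the clock and glucocorticoid lists, and the enrichment of terms on the higher side without Kit. Alternatives for normalized values did not apply to counts. In groups of 4, the sample farthest from the others was compared with Dixon's critical value. Random gene lists matched on expression numbered 1000. Terms deposited with the tables were tested by the hypergeometric distribution, after the result was seen.

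The method was tested on simulated data with the depth and spread of each experiment and 200 changed genes. Of genes changed 1.5-fold, 2-fold and 4-fold, edgeR recovered 30 of 67, 38 of 67 and 58 of 66 in the sorted design, with 12 false among 138 calls. It recovered 3 of 67, 13 of 67 and 49 of 66 in the knockout design (8 false of 73) and 14 of 67, 44 of 67 and 55 of 66 in the MCD design (8 false of 121). DESeq2 made 64 false of 197, 47 of 139 and 42 of 185 calls. Tables were read and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.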

Results

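RNA sequencing was done on liver sinusoidal endothelial cells (LSECs), the fenestrated endothelium that lines the sinusoids, from male mice. The 20 samples form 6 groups in 3 experiments. In the first, LSECs of untreated wild-type mice were sorted into c-Kit negative and c-Kit positive cells, with 3 samples each. The second compared LSECs of Kit-CT control mice and Kit-KO mice after tamoxifen, the drug used to switch on an inducible Cre recombinase, with 3 samples each. The third compared LSECs of wild-type mice kept for 4 weeks on the MCD diet, a methionine- and choline-deficient diet that gives steatohepatitis, after infusion of c-Kit negative or c-Kit positive cells, with 4 samples each. Total counts per sample were 16543033 to 26575602 in the sorted cells, 14120131 to 16847390 in the knockout experiment and 16680968 to 20815597 in the MCD experiment. Nothing in the labels says that the samples of a group came from separate mice, so the p-values may measure only technical spread. Values below are CPM, counts scaled to a common library size, as mean ± SD and log2 fold changes ± SE, with n = 3 per group (4 in the MCD experiment). Adjusted p-values of genes are from edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment over all genes tested, and adjusted p-values of gene lists are from camera, both two-sided. Coordinates are those of GRCm38 (mm10) with GENCODE M21 genes.

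Kit itself (ENSMUSG00000005672, chromosome 5, 75574916 to 75656722), which encodes the receptor tyrosine kinase for stem cell factor, was expressed in every library. In the sorted cells it stood at 120 ± 29.4 CPM in c-Kit negative and 958 ± 53 CPM in c-Kit positive cells, a 7.98-fold difference (log2 fold change 3.0 ± 0.18, adjusted p = 0.000117). In the knockout experiment it stood at 558 ± 116 CPM in Kit-CT and 288 ± 44.1 CPM in Kit-KO (log2 fold change -0.95 ± 0.20, adjusted p = 0.0576). Every Kit-KO library lay below every Kit-CT library. The adjusted p was 0.062 with a stricter expression filter, 0.0266 without a filter on low counts, 0.0449 with the newer quasi-likelihood method and 0.000343 in DESeq2. With 1 library left out it was 0.0168 without Kit-CT replicate 2 and missed the threshold in the 5 other fits, from 0.108 without Kit-KO replicate 1 to 0.268 without Kit-KO replicate 2. Kit was counted over the whole gene, and the part deleted in Kit-KO is not given in the sources used here. All 13 genes of a sinusoidal endothelial identity list were also negative in Kit-KO, with a median log2 fold change of -0.62. How much of the Kit difference goes with a lower share of LSECs was not tested. In the MCD experiment Kit stood at 466 ± 76.6 CPM after negative infusion and 418 ± 39.3 CPM after positive infusion (log2 fold change -0.16 ± 0.12, adjusted p = 0.524).

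**Figure D1:**
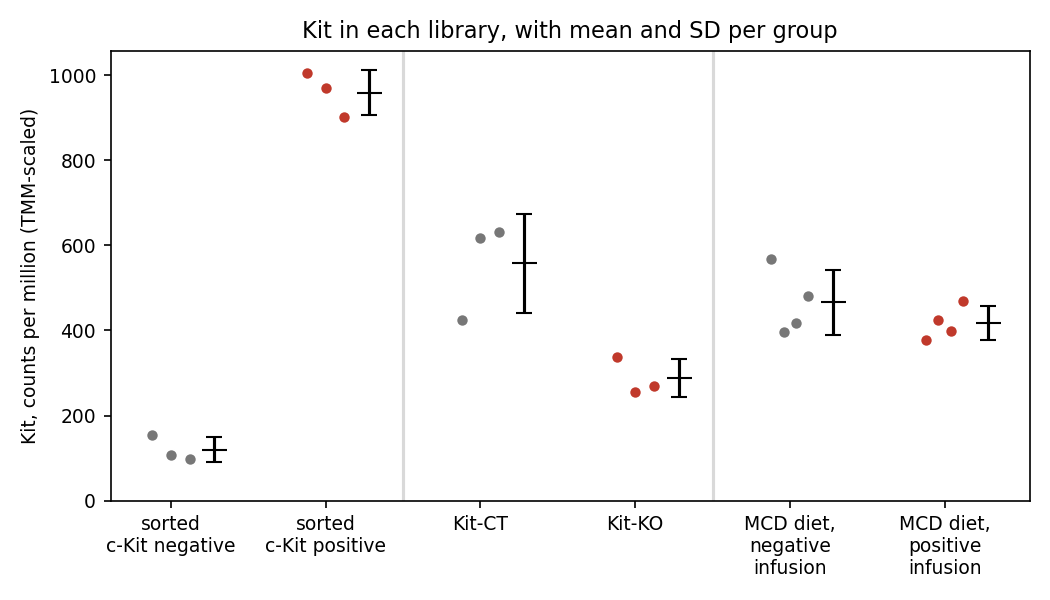
Kit in CPM for each library of the 6 groups, with the mean and SD of each group. The sorted c-Kit positive libraries lie at 900.3 to 1004.4 CPM and the sorted c-Kit negative libraries at 98.6 to 153.6 CPM. The Kit-KO libraries lie at 255.6 to 338.3 CPM, below the Kit-CT libraries at 424.4 to 632.3 CPM.

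The first comparison asks how c-Kit positive LSECs differ from c-Kit negative LSECs in untreated wild-type mice. The c-Kit positive cells had higher levels of sinusoidal identity genes, of the pericentral Wnt ligand gene Wnt2 and of cell-division genes, and also of mast cell and progenitor markers. The c-Kit negative libraries had higher levels of arterial and periportal endothelial genes, cholesterol synthesis genes and matrix genes, and also of bile duct, lymphatic and stellate cell markers. With an estimated correlation no list was called (smallest adjusted p = 0.56). Of 14096 genes tested, 1921 were higher and 2624 were lower in c-Kit positive cells. With a log2 fold change of at least 1 as a further condition, 263 were higher and 1578 lower.

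All 13 sinusoidal identity genes were higher in c-Kit positive cells (13 higher, 0 lower, also when adjusted over the list alone), with a median log2 fold change of 0.78 (adjusted p = 1.26e-08, and adjusted p = 0.82 with an estimated correlation). Stab2 (chromosome 10, 86841198 to 87008025), a scavenger receptor for hyaluronan, went from 3130 ± 236 to 6500 ± 438 CPM (log2 fold change 1.06 ± 0.09, adjusted p = 0.000173). Lyve1, another hyaluronan receptor, doubled from 325 ± 7.53 to 650 ± 61.7 CPM (log2 fold change 1.0 ± 0.08, adjusted p = 0.000113). Mrc1, the mannose receptor, went from 2030 ± 175 to 3710 ± 234 CPM (log2 fold change 0.87 ± 0.09, adjusted p = 0.000363). Of 11 pericentral endothelial markers, 6 were higher, 1 was lower and 4 did not pass, the same over the list alone (median 0.89, adjusted p = 0.0129, and adjusted p = 0.83 with an estimated correlation). The call was lost without c-Kit negative replicate 1 (adjusted p = 0.082). Wnt2 (chromosome 6, 17988940 to 18030585), whose product maintains pericentral hepatocyte gene expression, went from 46.7 ± 2.26 to 292 ± 34.4 CPM (log2 fold change 2.64 ± 0.09, adjusted p = 1.55e-05). Rab3b, a vesicle GTPase gene (log2 fold change 2.32 ± 0.23, adjusted p = 0.000735), and Lhx6, a homeobox gene (2.12 ± 0.31, adjusted p = 0.00465), were also higher. Vwf, the gene of von Willebrand factor, was the lower one, from 1160 ± 460 to 166 ± 41.8 CPM (log2 fold change -2.80 ± 0.40, adjusted p = 0.00445).

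Of 13 periportal and portal endothelial markers, 0 were higher, 12 were lower and 1 did not pass, the same over the list alone, with a median log2 fold change of -1.56 (adjusted p = 1.44e-08, and adjusted p = 0.56 with an estimated correlation). Gja5, the gap junction gene of arterial endothelium, went from 46.7 ± 12.5 to 3.05 ± 0.533 CPM (log2 fold change -3.92 ± 0.24, adjusted p = 0.00012). Adgrg6, an adhesion G protein-coupled receptor gene, went from 256 ± 50.2 to 11.1 ± 5.21 CPM (-4.51 ± 0.38, adjusted p = 0.000677). Bmx, a kinase gene of arterial endothelium, was also lower (-4.26 ± 0.42, adjusted p = 0.000694). So was Clu, the clusterin gene (2800 ± 146 to 258 ± 98 CPM, -3.44 ± 0.34, adjusted p = 0.00112). Of 14 Notch pathway genes, 2 were higher, 8 lower and 4 did not pass, the same over the list alone. Among them the ligand gene Jag1 went from 154 ± 12.1 to 26.7 ± 4.85 CPM (-2.52 ± 0.14, adjusted p = 6.78e-05). Lfng, a glycosyltransferase that modifies Notch, went from 21.4 ± 1.76 to 74 ± 14.6 CPM (1.79 ± 0.15, adjusted p = 0.000269). As a group the Notch list did not pass (median -0.64, adjusted p = 0.14).

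Proliferation genes were higher in c-Kit positive cells for 18 of 22, with 4 not passing, the same over the list alone (median log2 fold change 0.68, adjusted p = 1.05e-06, and adjusted p = 0.82 with an estimated correlation). Their levels were low, and mast cell and progenitor markers were higher in the same libraries (median 2.08). Which cells carried the proliferation genes was not tested. Kif11, a mitotic kinesin gene, went from 3.32 ± 0.29 to 8.74 ± 0.318 CPM (1.40 ± 0.14, adjusted p = 0.00032). Bub1, a spindle checkpoint kinase gene, went from 0.823 ± 0.091 to 3.02 ± 0.654 CPM (1.87 ± 0.26, adjusted p = 0.0015). Ube2c, a mitotic ubiquitin-conjugating enzyme gene, went from 1.69 ± 0.395 to 4.88 ± 0.896 CPM (1.53 ± 0.25, adjusted p = 0.00275). Of 15 antigen presentation genes, 5 were higher and 10 did not pass, the same over the list alone (median 0.22, adjusted p = 0.0141, and adjusted p = 0.88 with an estimated correlation). The list lost its call without c-Kit positive replicate 1 (adjusted p = 0.0506). Ciita, the master regulator of MHC class II genes, went from 8.61 ± 3.2 to 26.4 ± 3.38 CPM (1.62 ± 0.28, adjusted p = 0.00608). H2-Eb1, a class II gene, went from 52.3 ± 18.9 to 137 ± 22.1 CPM (1.39 ± 0.29, adjusted p = 0.0164), but missed the threshold without c-Kit negative replicate 2 (0.0606) or positive replicate 2 (0.0624). H2-Aa, also among the 5, missed it without negative replicates 2 (0.107) or 3 (0.0833) or positive replicates 1 (0.0734), 2 (0.12) or 3 (0.0569). H2-Ab1, among them too, missed it without negative replicates 2 (0.0804) or 3 (0.0623) or positive replicates 1 (0.0526) or 2 (0.0894). Flt3, a receptor gene of hematopoietic progenitors and dendritic cells (2.08 ± 0.21), and Ighm, a B cell gene (2.84-fold), were higher in the same libraries. Of 12 endoplasmic reticulum stress genes, 2 were higher and 10 did not pass, the same over the list alone: Herpud1 (0.51 ± 0.05, adjusted p = 0.000392) and Manf (0.27 ± 0.06, adjusted p = 0.014). That list's median was 0.20 (adjusted p = 0.0318, and adjusted p = 0.82 with an estimated correlation). Its call was lost without c-Kit negative replicate 1 (0.0656) or positive replicate 2 (0.0836), and with a stricter expression filter (0.0602).

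Cholesterol synthesis genes were lower in c-Kit positive cells for 11 of 18, with 7 not passing, the same over the list alone (median log2 fold change -0.48, adjusted p = 0.000529, and adjusted p = 0.83 with an estimated correlation). Sqle, the gene of squalene epoxidase, went from 46.1 ± 3.08 to 12.8 ± 4.04 CPM (-1.84 ± 0.23, adjusted p = 0.00169). Lss, which encodes lanosterol synthase (-1.59 ± 0.26, adjusted p = 0.00429), and Fdft1, which encodes squalene synthase (-1.11 ± 0.14, adjusted p = 0.00132), were lower with it. Of 17 extracellular matrix and fibrosis genes, 3 were higher, 9 were lower and 5 did not pass; adjusted over the list alone, 4 were higher and 12 lower. The median was -0.65 (adjusted p = 0.0281, and adjusted p = 0.83 with an estimated correlation), and the call was lost without c-Kit positive replicate 1 (0.0506) and with the replicate number as a block (0.0503). Thbs1, the thrombospondin 1 gene, went from 33.5 ± 1.44 to 5.41 ± 1.38 CPM (-2.62 ± 0.17, adjusted p = 7.37e-05). Ccn2, a matricellular growth factor gene, went from 155 ± 11 to 55.1 ± 16 CPM (-1.49 ± 0.23, adjusted p = 0.00554). Lox, the collagen cross-linking enzyme gene, went from 10.6 ± 2.78 to 1.21 ± 0.964 CPM (-3.08 ± 0.52, adjusted p = 0.00594, and -4 to -2.75 with 1 library left out). In the same libraries the cholangiocyte markers had a median of -4.25 and the stellate cell and fibroblast markers -0.53. Which cells carried the cholesterol synthesis and matrix genes was not tested. Ribosomal protein genes were lower for 2 of 77, Rps16 and Rps19, and for 0 when adjusted over the list alone. Without c-Kit negative replicates 2 or 3 or positive replicates 1 or 3, Rps16 (0.0778, 0.0765, 0.0831 and 0.119) and Rps19 (0.116, 0.0935, 0.0566 and 0.114) missed the threshold, as did Rps16 with the replicate number as a block (0.0507). The median of the 77 was -0.10 (adjusted p = 0.0141, and adjusted p = 0.88 with an estimated correlation), and the call was lost without c-Kit negative replicate 3 (0.0635) or positive replicate 3 (0.247).

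Lists of signalling and vascular genes that did not pass as groups held single genes with large differences. Of 12 flow response and vasoregulation genes, 1 was higher, 5 were lower and 6 did not pass, the same over the list alone; the median was 0.11, the mean -0.46 and the test downward (adjusted p = 0.529). In that list Ednrb, an endothelin receptor gene, went from 340 ± 70.9 to 58.2 ± 18.9 CPM (-2.54 ± 0.29, adjusted p = 0.00193). Edn1, the endothelin 1 gene, went from 51.1 ± 12.2 to 13.2 ± 1.36 CPM (-1.96 ± 0.19, adjusted p = 0.000596). Of 13 ERK feedback genes, 4 were higher, 2 were lower and 7 did not pass, the same over the list alone; the median was 0.01, the mean -0.15 and the test upward (adjusted p = 0.529). Dusp4, an ERK phosphatase gene, went from 17.7 ± 1.6 to 62.2 ± 3.71 CPM (1.81 ± 0.08, adjusted p = 2.72e-05). Of 15 angiocrine factor genes, 4 were higher and 6 lower, and 4 and 8 over the list alone (median -0.20, adjusted p = 0.378). Vegfc, a lymphangiogenic growth factor gene, went from 51.7 ± 4.99 to 5.7 ± 1.21 CPM (-3.17 ± 0.16, adjusted p = 3.45e-05). Of 13 capillarization and basement membrane genes, 4 were higher and 7 lower, the same over the list alone (median -0.43, adjusted p = 0.271). Ly6a, the Sca-1 gene, went from 399 ± 36.1 to 93.1 ± 3.9 CPM (-2.10 ± 0.08, adjusted p = 1.55e-05).

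Markers of other cell types differed between the sorted groups in both directions, beside the endothelial groups above. All 6 cholangiocyte markers were lower in c-Kit positive cells, also over the list alone (median log2 fold change -4.25, adjusted p = 2.94e-05, and adjusted p = 0.82 with an estimated correlation). Spp1, the osteopontin gene, went from 1880 ± 160 to 82.8 ± 41.3 CPM (-4.50 ± 0.46, adjusted p = 0.00138). Epcam, an epithelial adhesion gene, went from 84.9 ± 9.73 to 4.13 ± 1.57 CPM (-4.34 ± 0.28, adjusted p = 0.00022). All 4 lymphatic endothelial markers were lower, also over the list alone (median -3.19, adjusted p = 0.0281, 0.0602 with a stricter expression filter, and adjusted p = 0.83 with an estimated correlation). Of these, Pdpn missed the threshold without c-Kit negative replicates 1 (0.113), 2 (0.0885) or 3 (0.119) or positive replicates 1 (0.0984) or 2 (0.0564). Mmrn1 missed it without negative replicates 1 (0.0637) or 3 (0.0639) or positive replicate 2 (0.0736). Prox1, the lymphatic master regulator, went from 161 ± 23.7 to 24.7 ± 9.71 CPM (-2.70 ± 0.33, adjusted p = 0.00267). Of 11 stellate cell and fibroblast markers, 7 were lower and 4 did not pass, and 9 were lower over the list alone (median -0.53, adjusted p = 0.000516, and adjusted p = 0.83 with an estimated correlation). The pericyte gene Rgs5 went from 495 ± 23.6 to 275 ± 43 CPM (-0.85 ± 0.11, adjusted p = 0.00121). Of 8 monocyte and neutrophil markers, 1 was higher, 5 lower and 2 did not pass (2 and 5 over the list alone), with a median of -3.28 that missed the threshold (adjusted p = 0.0556). S100a8, a calprotectin subunit gene, was at 17.4 ± 3.71 and 0.857 ± 0.408 CPM (-4.30 ± 0.34, adjusted p = 0.000202). The 15 hepatocyte markers (median 0.72, adjusted p = 0.0824) and the 12 Kupffer cell and macrophage markers (median -0.58, adjusted p = 0.529) held 0 genes past the edgeR threshold.

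Some blood cell markers were higher in c-Kit positive cells. Of 7 mast cell and progenitor markers tested, 6 were higher and 1 did not pass, the same over the list alone, with a median log2 fold change of 2.08 that was the same with genes at 0 counts set to their bound (adjusted p = 0.00108, and adjusted p = 0.56 with an estimated correlation). Cpa3, the mast cell carboxypeptidase gene, had 0 counts in all c-Kit negative libraries and 305 counts in the c-Kit positive ones, at least 84.3-fold higher with a floor of 3 counts over the group. Tpsb2, a mast cell tryptase gene, had 0 and 210 counts, at least 58.0-fold higher. Flt3 went from 5.09 ± 1.2 to 21.4 ± 3.84 CPM (2.08 ± 0.21, adjusted p = 0.000445). Mpo, the myeloperoxidase gene, went from 1.48 ± 0.544 to 6.65 ± 1.53 CPM (2.19 ± 0.32, adjusted p = 0.00176). Of 8 B cell markers, 2 were higher, 1 was lower and 5 did not pass, the same over the list alone (median 0.54, adjusted p = 0.14). Ighm, the immunoglobulin mu gene, went from 52 ± 10.2 to 147 ± 25.8 CPM, 2.84-fold (adjusted p = 0.00205). Of 5 erythroid markers, 4 globin genes were higher (5 over the list alone; median 2.88, adjusted p = 0.0678 as a list). Hba-a1 was at 19.6 ± 6.96 and 156 ± 133 CPM (3.0 ± 0.82, adjusted p = 0.0418, and 2.11 to 3.47 with 1 library left out), and missed the threshold without c-Kit negative replicates 1 (0.134), 2 (0.0895) or 3 (0.133), without positive replicates 1 (0.0935) or 3 (0.0803), and with the replicate number as a block (0.211). Hbb-bs (0.101 to 0.149), Hbb-bt (0.0797 to 0.135) and Hba-a2 (0.0924 to 0.143) missed it in the same left-out fits. With the block they missed it too (0.227, 0.117 and 0.204).

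Outside the lists, the genes with the largest differences that met the naming rule included Trpv3, a cation channel gene, on the higher side (1.42 ± 0.301 to 18.5 ± 2.15 CPM, 3.71 ± 0.19, adjusted p = 3.25e-05). The others on that side included Olfr1396 (3.32 ± 0.26, adjusted p = 0.000123), Ifitm10 (2.87 ± 0.21, adjusted p = 0.000123) and Ramp3, a receptor activity-modifying protein gene (2.60 ± 0.17, adjusted p = 7.16e-05). On the lower side they included Clca3a2 (7.58 ± 0.521 to 0.217 ± 0.0267 CPM, -5.10 ± 0.21, adjusted p = 2.34e-05), Cldn6, a tight junction gene (-4.93 ± 0.44, adjusted p = 0.000556, and -5.62 to -4.5 with 1 library left out), and Myo5c, a myosin gene of epithelial cells (-4.77 ± 0.17, adjusted p = 1.55e-05). Nrg1, the neuregulin 1 gene, was lower as well (53.2 ± 8.21 to 1.9 ± 1.11 CPM, -4.75 ± 0.36, adjusted p = 0.000388, and -5.39 to -4.52 with 1 library left out). At 6610 genes (46.9% of those tested) the groups did not overlap, where chance gives 10%. Leaving out any 1 library gave 1294 to 2056 higher and 2079 to 2532 lower genes. The replicate numbers paired the sorted samples by the values themselves, and with the number as a block 2509 genes were higher and 2957 lower.

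**Figure D2:**
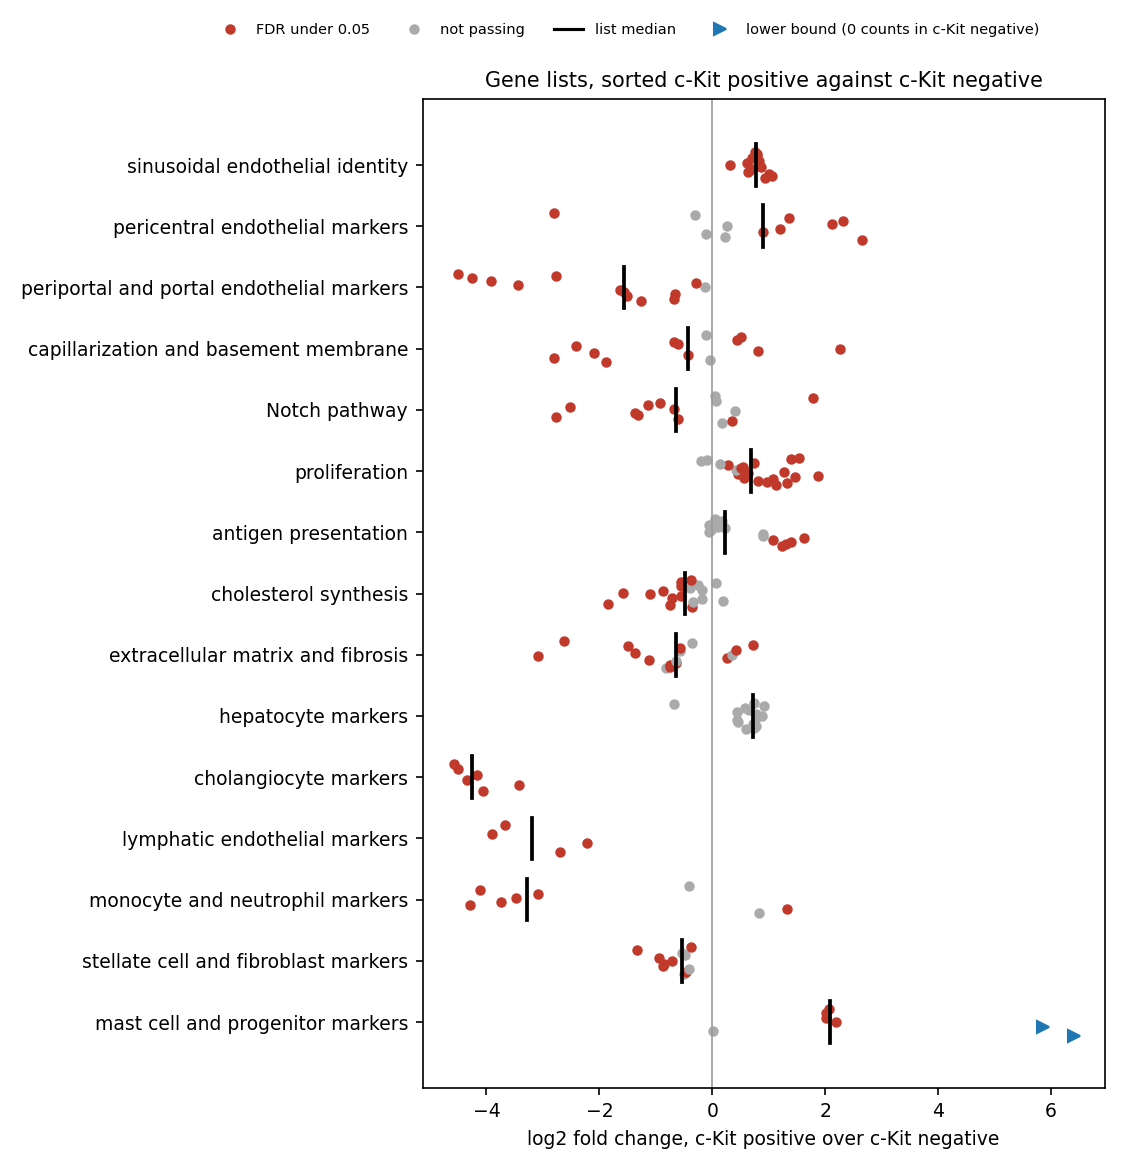
Log2 fold change (c-Kit positive over c-Kit negative LSECs, n = 3 each) of the members of 15 gene lists, 1 point per gene. Red points passed an adjusted p of 0.05, grey points did not, black bars are list medians and blue triangles are the lower bounds of Cpa3 and Tpsb2. Sinusoidal identity genes lie to the right of 0 with a median of 0.78, and cholangiocyte markers lie to the left with a median of -4.25.

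The second comparison asks what LSECs express after inducible deletion of Kit. Hepatocyte genes were higher in Kit-KO than in Kit-CT libraries, among them 2 fibrinogen chain genes, an apolipoprotein gene and the arginase gene Arg1. Sinusoidal identity genes lay lower as a group, with no member past the threshold over all genes. With an estimated correlation neither list was called (adjusted p = 0.22 for hepatocyte markers and 0.49 for sinusoidal identity genes). Of 13454 genes tested, 181 rose and 7 fell in Kit-KO. The mitochondrially encoded share of counts was 4.77% ± 2.02 in Kit-CT and 7.92% ± 1.2 in Kit-KO.

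Hepatocyte markers rose for 12 of 15, with 3 not passing and 15 rising when adjusted over the list alone (median log2 fold change 2.10, adjusted p = 4.62e-25, and adjusted p = 0.22 with an estimated correlation). Fga, a fibrinogen chain gene, rose from 39.3 ± 9.55 to 189 ± 35.5 CPM (2.27 ± 0.22, adjusted p = 0.00262). Fgg, another fibrinogen chain gene, rose from 30.7 ± 5.71 to 148 ± 30.8 CPM (2.27 ± 0.20, adjusted p = 0.00261). Apoa2, an apolipoprotein gene of high-density lipoprotein, rose from 19.2 ± 3.87 to 88.7 ± 28.6 CPM (2.20 ± 0.26, adjusted p = 0.00666). Periportal hepatocyte markers rose for 6 of 10, with 9 rising over the list alone (median 2.07, adjusted p = 8.73e-13, and adjusted p = 0.22 with an estimated correlation). Among these were Arg1, the arginase of the urea cycle (11.7 ± 0.404 to 76.8 ± 27.5 CPM, 2.71 ± 0.27, adjusted p = 0.00377), and Hal, the histidine ammonia-lyase gene (2.63 ± 0.29, adjusted p = 0.00452). Of 7 pericentral hepatocyte markers, 1 rose and 6 did not pass, with 4 rising over the list alone (median 2.31, adjusted p = 0.0276, and adjusted p = 0.49 with an estimated correlation). That call was lost without Kit-CT replicate 2 (0.0546), Kit-CT replicate 3 (0.0608) or Kit-KO replicate 2 (0.0567), and with a stricter expression filter (0.0695). The member that rose was Cyp1a2, a cytochrome P450 gene (1.52 ± 0.504 to 9.88 ± 3.95 CPM, adjusted p = 0.0241). Cyp1a2 missed the threshold without Kit-CT replicates 3 (0.0783) or 4 (0.0796) and without Kit-KO replicates 1 (0.114) or 2 (0.0968).

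Among the largest increases outside those lists were Sec14l2, a lipid-binding protein gene (1.89 ± 0.398 to 18.4 ± 4.86 CPM, 3.27 ± 0.32, adjusted p = 0.00309), and Dpyd, which encodes the enzyme that starts pyrimidine breakdown (2.76 ± 0.924 to 22.9 ± 5.14 CPM, 3.05 ± 0.33, adjusted p = 0.00427). Cyp2d26, a cytochrome P450 gene, rose too (3.11 ± 0.617 to 23.8 ± 5.2 CPM, 2.93 ± 0.28, adjusted p = 0.00262). The immunoglobulin gene Ighg1 had 2 counts in Kit-CT and 247 in Kit-KO, a ratio of 121 (95% exact Clopper-Pearson interval 33.2 to 1010; adjusted p = 0.00991). With 1 library left out the log2 fold change of Ighg1 was 6.11 to 9.3 and its adjusted p at most 0.0467. Acsl1, a fatty acid activation gene, rose from 27.5 ± 1.24 to 61.1 ± 8.08 CPM (1.15 ± 0.15, adjusted p = 0.00893), but missed the threshold without Kit-KO replicate 2 (1.04, adjusted p = 0.0514). Of 15 lipogenesis genes, 1 rose and 14 did not pass, with 4 rising over the list alone (median 0.35, adjusted p = 0.000501, and adjusted p = 0.22 with an estimated correlation). The member that rose, Dgat2, a triglyceride synthesis gene, went from 4.49 ± 1.91 to 23.9 ± 5.47 CPM (2.42 ± 0.35, adjusted p = 0.0136), and missed the threshold without Kit-CT replicate 4 (0.0607) or Kit-KO replicate 2 (0.0688). All 12 oxidative stress response genes were positive, with 1 past the threshold and 2 over the list alone (median 0.46, adjusted p = 0.000393, and adjusted p = 0.49 with an estimated correlation). The 1 was Gpx1, a glutathione peroxidase gene (adjusted p = 0.0359), which missed the threshold without Kit-CT replicates 3 (0.112) or 4 (0.129) and without Kit-KO replicates 1 (0.115) or 2 (0.146). Of 15 fatty acid oxidation genes, 0 passed in edgeR and 1 rose over the list alone (median 0.36, adjusted p = 0.0316, and adjusted p = 0.49 with an estimated correlation). The call of this last list was lost without Kit-CT replicate 2 (0.0806), Kit-CT replicate 3 (0.118) or Kit-KO replicate 1 (0.104). The hepatocyte markers had a median of 2.10 in the same libraries. Whether the lipid and oxidative stress genes rose in LSECs or with hepatocyte RNA was not tested.

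Markers of some blood cells and of duct cells lay higher in Kit-KO as lists, without a member past the threshold over all genes. The 12 Kupffer cell and macrophage markers had a median of 1.55 (adjusted p = 9.41e-06), the 8 monocyte and neutrophil markers 1.85 (adjusted p = 0.000526) and the 6 cholangiocyte markers 1.08 (adjusted p = 0.00324), with 0 passing in edgeR over each list alone. The 8 B cell markers had a median of 1.39 (adjusted p = 0.000221), with 2 rising over the list alone. For each of these 4 lists the value was adjusted p = 0.49 with an estimated correlation. The 11 T and NK cell markers (median 0.55, adjusted p = 0.143), the 5 erythroid markers (2.10, adjusted p = 0.064) and the 4 platelet markers (0.30, adjusted p = 0.473) did not pass as lists. Lyz2, the lysozyme gene of myeloid cells, stood at 214 ± 178 and 657 ± 179 CPM (1.61 ± 0.67, adjusted p = 0.363, and 1.2 to 2.52 with 1 library left out, adjusted p from 0.0519 to 0.633). Spp1 stood at 305 ± 152 and 755 ± 251 CPM (1.31 ± 0.42, adjusted p = 0.256) and Ighm at 21.4 ± 9.12 and 63.8 ± 22.3 CPM (1.57 ± 0.39, adjusted p = 0.146). In DESeq2 Spp1 (0.00382) and Ighm (0.000399) passed. The 11 stellate cell and fibroblast markers had a median of -0.22 (adjusted p = 0.204). All 13 mitochondrially encoded genes were positive with 0 passing in edgeR (median 0.63, adjusted p = 6.39e-05, and adjusted p = 0.49 with an estimated correlation). The 77 ribosomal protein genes had a median of 0.10 with 0 passing in edgeR (adjusted p = 0.00906, and adjusted p = 0.82 with an estimated correlation). The call of the ribosomal list was lost without Kit-CT replicate 4 (0.484), Kit-KO replicate 1 (0.229) or Kit-KO replicate 2 (0.141).

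On the lower side, Cd93, a C-type lectin-like receptor gene of endothelium, fell from 705 ± 39 to 393 ± 33.7 CPM (-0.84 ± 0.14, adjusted p = 0.0273). Adm, the gene of the vasodilator adrenomedullin, fell from 71.5 ± 11.8 to 37.8 ± 4.26 CPM (-0.92 ± 0.17, adjusted p = 0.0356). Lpin3, a phosphatidate phosphatase gene, fell from 50.8 ± 5.85 to 26.5 ± 2.14 CPM (-0.94 ± 0.15, adjusted p = 0.0241). Lrrc8a, which encodes a volume-regulated anion channel subunit, fell from 158 ± 21.5 to 92.7 ± 5.15 CPM (-0.77 ± 0.14, adjusted p = 0.0356). Tnfaip8l1 (-0.86 ± 0.16, adjusted p = 0.0414) and Tom1l2 (-0.62 ± 0.12, adjusted p = 0.0471) fell with them. The seventh was Sftpa1, a surfactant protein gene at 2.95 ± 0.681 and 0.149 ± 0.0991 CPM, which lies outside the naming rule and was chosen after its values were seen. Cd93 passed without Kit-CT replicate 2 only, and missed the threshold without Kit-CT replicates 3 (0.0556) or 4 (0.0735) and without Kit-KO replicates 1 (0.136), 2 (0.113) or 3 (0.0517). Adm missed it without Kit-CT replicate 3 (0.0971) and without Kit-KO replicates 1 (0.14), 2 (0.175) or 3 (0.0517). Lpin3 missed it without Kit-CT replicates 3 (0.0783) or 4 (0.055) and Kit-KO replicates 1 (0.0874), 2 (0.11) or 3 (0.0738). Lrrc8a missed it without Kit-CT replicates 3 (0.0611) or 4 (0.0983) and Kit-KO replicates 1 (0.124), 2 (0.156) or 3 (0.0841). Tnfaip8l1 missed it without Kit-CT replicates 2 (0.0683) or 4 (0.129) and Kit-KO replicates 1 (0.143), 2 (0.153) or 3 (0.128). Tom1l2 missed it without Kit-CT replicates 2 (0.0781), 3 (0.0992) or 4 (0.125) and Kit-KO replicates 1 (0.198), 2 (0.111) or 3 (0.125). With the replicate number as a block, Cd93 (0.0607), Lrrc8a (0.0781), Tnfaip8l1 (0.0741) and Tom1l2 (0.14) missed it as well. In the same libraries the sinusoidal identity genes had a median of -0.62 and the hepatocyte markers 2.10. Whether any of these genes fell beyond what a lower share of LSECs would give was not tested.

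The 13 sinusoidal identity genes all had negative values, with 0 passing over all genes in edgeR and 9 falling over the list alone (median log2 fold change -0.62, adjusted p = 6.07e-07, and adjusted p = 0.49 with an estimated correlation). Stab2 stood at 5150 ± 1070 and 3240 ± 482 CPM (-0.67 ± 0.22, adjusted p = 0.225). Oit3, an LSEC-enriched gene, stood at 2470 ± 508 and 1510 ± 184 CPM (-0.72 ± 0.21, adjusted p = 0.172). Of 13 ERK feedback genes 12 were negative and 0 passed in edgeR, also over the list alone (median -0.46, adjusted p = 0.00289, and adjusted p = 0.39 with an estimated correlation). Dusp4 stood at 88.1 ± 34.9 and 41.7 ± 7.05 CPM (-1.08 ± 0.28, adjusted p = 0.143). Spred2, a Ras-ERK inhibitor gene, stood at 120 ± 25.4 and 84.3 ± 2.32 CPM (-0.52 ± 0.16, adjusted p = 0.209). Of these genes Stab2 (0.0213), Oit3 (0.00983) and Dusp4 (0.0051) passed in DESeq2. Of 12 endoplasmic reticulum stress genes 11 were negative and 0 passed in edgeR, also over the list alone (median -0.40, adjusted p = 0.00256, and adjusted p = 0.49 with an estimated correlation). Of 12 flow response and vasoregulation genes 1, Adm, fell and 11 did not pass, the same over the list alone (median -0.26, adjusted p = 0.0276, and adjusted p = 0.49 with an estimated correlation). The call of the flow list was lost without Kit-CT replicates 3 (0.114) or 4 (0.0541), without Kit-KO replicates 1 (0.0864) or 3 (0.0931), and with a stricter expression filter (0.0584). Whether the ERK feedback, endoplasmic reticulum stress and flow lists fell beyond the shift of the sinusoidal identity genes was not tested.

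At 2803 genes (20.8% of those tested) the Kit-CT and Kit-KO groups did not overlap, where chance gives 10%. The 181 higher and 7 lower genes became 290 and 33 without Kit-CT replicate 2, 127 and 4 without Kit-CT replicate 3, and 105 and 1 without Kit-CT replicate 4. They became 81 and 0 without Kit-KO replicate 1, 61 and 3 without Kit-KO replicate 2, and 157 and 4 without Kit-KO replicate 3. DESeq2 gave 629 and 135, and an edgeR fit with a hepatocyte score as a covariate, chosen after seeing the data, 0 and 0. That score separates the groups, and without it 1961 genes had an unadjusted p under 0.05.

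**Figure D3:**
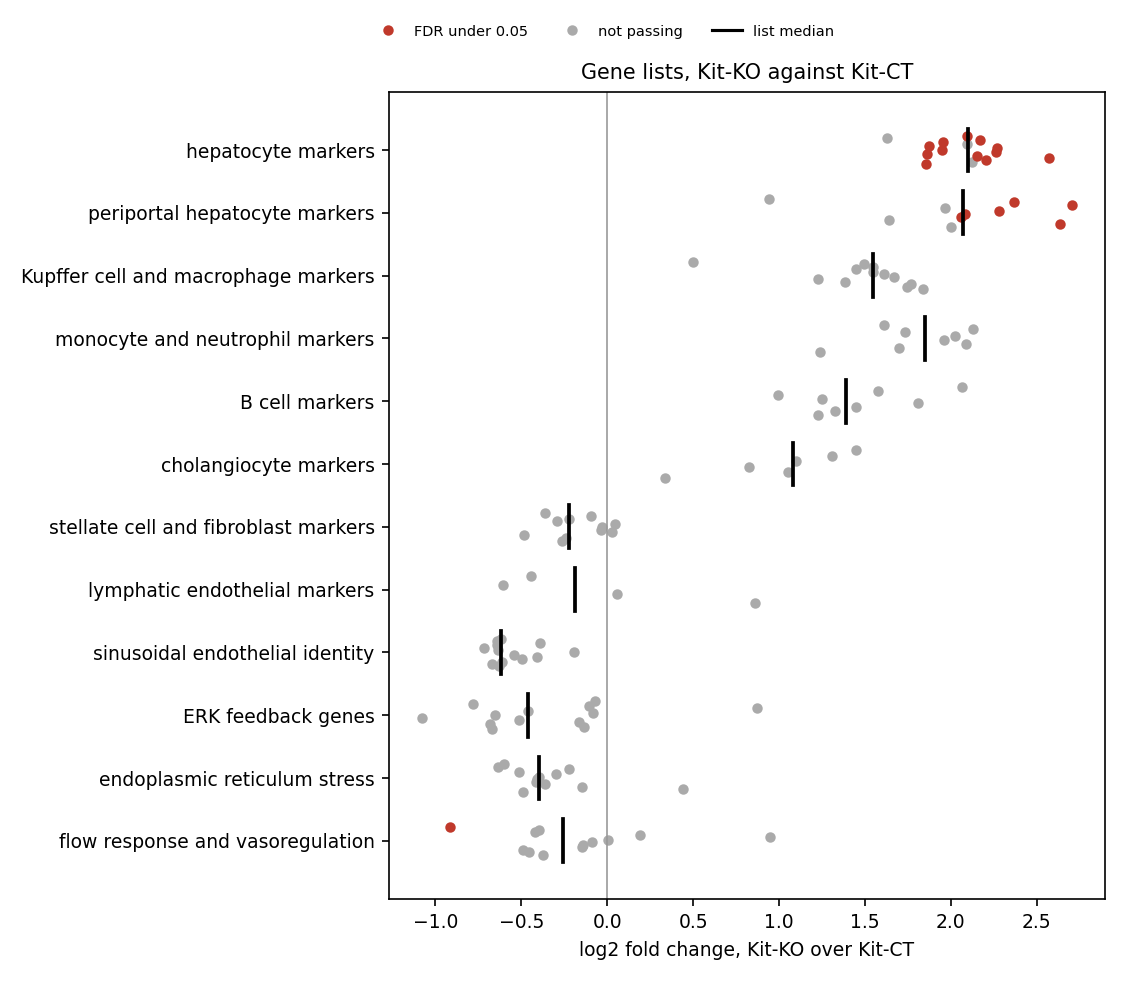
Log2 fold change (Kit-KO over Kit-CT LSECs, n = 3 each) of the members of 12 gene lists, 1 point per gene. Red points passed an adjusted p of 0.05, grey points did not, and black bars are list medians. Hepatocyte markers lie to the right of 0 with a median of 2.10, and all 13 sinusoidal identity genes lie to the left with a median of -0.62.

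The third comparison asks what LSECs of MCD-fed mice express after infusion of c-Kit positive in place of c-Kit negative cells. Inflammatory genes (adhesion molecules, chemokines and cytokines), and neutrophil, red cell and T or NK cell markers, lay lower as lists after positive infusion. Fatty acid oxidation genes, mitochondrially encoded genes and cholangiocyte markers lay higher as lists. With an estimated correlation none of these lists was called (adjusted p from 0.49 to 0.79), and the T or NK cell call and the last 3 were also lost without positive infusion replicate 1. No single gene of 13670 tested passed in edgeR: 0 were higher and 0 lower, with 2537 (18.6%) at an unadjusted p under 0.05. DESeq2 gave 331 higher and 453 lower, and the authors' deposited table has 260 higher and 368 lower of 22274 genes at its adjusted p under 0.05. The deposited adjusted p-values followed those of DESeq2 here, such as Tardbp (8.01e-09 against 6.15e-09) and Hbb-bs (0.00128 against 0.000985). The deposited counts are therefore not separate evidence beside DESeq2.

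All 18 genes of the adhesion molecule and chemokine list, which also holds cytokine genes, had negative values, with 0 past the edgeR threshold over all genes and 6 lower over the list alone (median log2 fold change -0.83, adjusted p = 9.69e-09, and adjusted p = 0.49 with an estimated correlation). Il1b, the interleukin 1 beta gene, stood at 172 ± 54 CPM after negative and 48.2 ± 15.8 CPM after positive infusion (-1.83 ± 0.29, adjusted p = 0.08). Ptgs2, the inducible cyclooxygenase gene, stood at 54.8 ± 18.9 and 18.7 ± 4.21 CPM (-1.55 ± 0.26, adjusted p = 0.0844, and 0.0342 without negative infusion replicate 2). The 8 monocyte and neutrophil markers were all negative, with 5 lower over the list alone (median -1.66, adjusted p = 2.08e-05, and adjusted p = 0.77 with an estimated correlation). Whether the inflammatory genes above fell in LSECs or with these myeloid cells was not tested. S100a9, a calprotectin subunit gene, stood at 260 ± 134 and 71.1 ± 5.56 CPM (-1.87 ± 0.32, adjusted p = 0.0844, and 0.0209 without negative infusion replicate 2). The 5 erythroid markers were all negative and all lower over the list alone (median -1.68, adjusted p = 8.88e-05, and adjusted p = 0.77 with an estimated correlation). Hbb-bs, a beta globin gene, stood at 22.7 ± 9.42 and 7.23 ± 3.69 CPM (-1.65 ± 0.39, adjusted p = 0.115). In DESeq2 Il1b (4.77e-08), Ptgs2 (1.31e-06), S100a9 (3.5e-07) and Hbb-bs (0.000985) passed. Of 9 T and NK cell markers 8 were negative and 4 lower over the list alone (median -1.32, adjusted p = 0.0396, and adjusted p = 0.79 with an estimated correlation). The T and NK cell call was lost without negative infusion replicate 6 (0.0782) and without positive infusion replicates 1 (0.0687), 3 (0.0609) or 6 (0.0535).

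Smaller shifts were called for other lists. The 18 interferon response genes had a median of -0.25 with 0 lower over the list alone in edgeR (adjusted p = 0.018), and the 12 endoplasmic reticulum stress genes -0.36 with 3 lower and 1 higher over the list alone (adjusted p = 0.018). Manf, an endoplasmic reticulum stress-induced factor gene, stood at 76.3 ± 14.9 and 48.3 ± 5.08 CPM (-0.66 ± 0.14, adjusted p = 0.102, 0.0479 without negative infusion replicate 2, and 0.00284 in DESeq2). The 77 ribosomal protein genes had a median of -0.10 (adjusted p = 0.000939). The 15 fatty acid oxidation genes had a median of 0.20 (adjusted p = 0.00558). Cpt1a, the gene of the enzyme that controls fatty acid entry into mitochondria, stood at 149 ± 52.3 and 239 ± 20.4 CPM (0.68 ± 0.23, adjusted p = 0.197). The 13 mitochondrially encoded genes were all positive (median 0.27, adjusted p = 0.00603), as were the 6 cholangiocyte markers (median 0.73, adjusted p = 0.0294), with 0 past the edgeR threshold in these 4 lists over the list alone. For each of these 6 lists the value was adjusted p = 0.79 with an estimated correlation. The interferon call was lost without negative infusion replicate 2 (0.259) or positive infusion replicates 1 (0.0687) or 4 (0.109). The endoplasmic reticulum call was lost without negative infusion replicate 6 (0.0661). The ribosomal call was lost without negative infusion replicates 2 (0.135) or 5 (0.0922) or positive infusion replicate 1 (0.088). The fatty acid oxidation call was lost without positive infusion replicate 1 (0.0687). The mitochondrial call was lost without negative infusion replicate 4 (0.089) or positive infusion replicate 1 (0.0613). The cholangiocyte call was lost without negative infusion replicate 2 (0.135) or positive infusion replicate 1 (0.088). Positive infusion replicate 1 had the highest mitochondrially encoded share of the 8 libraries (10.197%), and its mean log2 CPM of hepatocyte markers was 6.716, with the others of its group at 5.262 to 5.368.

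The genes with the smallest p, none past the threshold (adjusted p = 0.0713 for each), are given as values. Tardbp, an RNA-binding protein gene, stood at 144 ± 7.08 and 104 ± 1.65 CPM (-0.47 ± 0.06). Cry2, a repressor gene of the circadian clock, stood at 12.9 ± 0.705 and 29.4 ± 6.62 CPM (1.19 ± 0.15), and Pde4c, a cyclic AMP phosphodiesterase gene, at 11.1 ± 1.53 and 20.2 ± 0.52 CPM (0.86 ± 0.11). Mxd1, a MYC antagonist gene, stood at 187 ± 15.9 and 118 ± 9.76 CPM (-0.67 ± 0.09), and Pi16, a gene of adventitial fibroblasts, at 13.2 ± 2.18 and 5.58 ± 0.797 CPM (-1.24 ± 0.16). All 5 passed in DESeq2, from Tardbp (6.15e-09) to Mxd1 (7.98e-08). At 1636 genes (12% of those tested) the groups did not overlap, where chance gives 2.86%. Without negative infusion replicate 2, 26 genes were higher and 75 lower, among them all 5 of these genes, Tardbp at 0.0284, Cry2 at 0.0311, Pde4c at 0.0311, Mxd1 at 0.0299 and Pi16 at 0.0231. The counts were 2 and 5 without negative infusion replicate 6 (Pde4c at 0.0269 and Mxd1 at 0.0373) and 1 and 0 without positive infusion replicate 6. They were 4 and 5 without a filter on low counts.

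**Figure D4:**
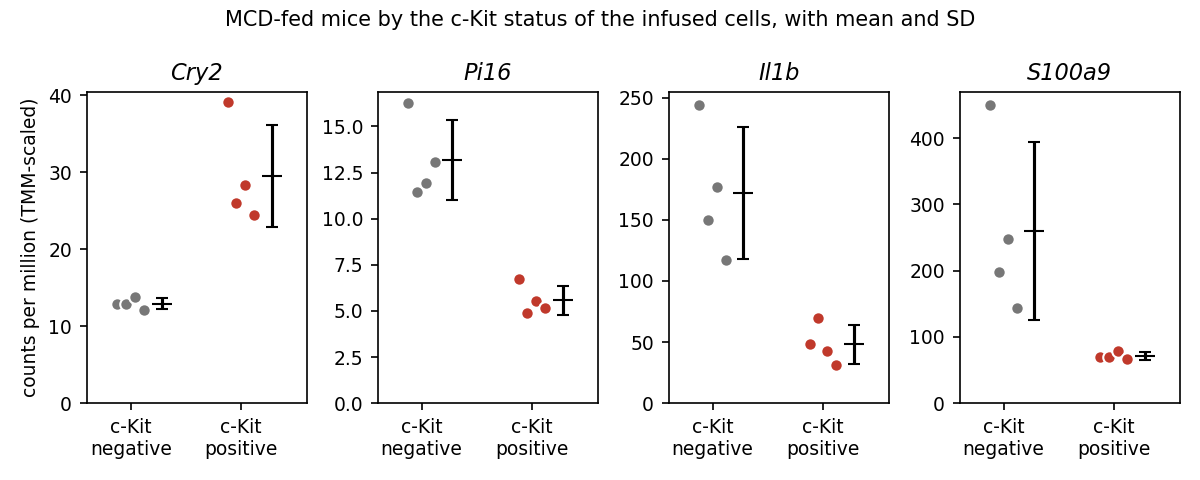
CPM of Cry2, Pi16, Il1b and S100a9 for each library of the MCD experiment, with the mean and SD of each group (n = 4). The positive infusion libraries average 29.4 CPM for Cry2 and 48.2 CPM for Il1b, against 12.9 and 172 CPM after negative infusion. None of the 4 genes passed the edgeR threshold (adjusted p from 0.0713 to 0.0844).

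The genes that separate the sorted cells were then followed into the other experiments, as those past the threshold with a log2 fold change of at least 1, without Kit. Of 1294 genes lower in c-Kit positive cells that were tested in the knockout experiment, 1131 had positive values in Kit-KO, with a median log2 fold change of 0.77 (camera p = 2.18e-19, 0.126 with an estimated correlation). The cholangiocyte markers, which belong to that set, had a median of 1.08 there. A score of the set did not separate the 3 Kit-KO from the 3 Kit-CT libraries by an exact permutation test (two-sided p = 0.2, where the smallest possible is 0.1). In the MCD experiment 1127 of 1415 such genes had positive values after positive infusion (median 0.49, camera p = 1.57e-11, 0.289 with an estimated correlation, exact permutation p = 0.229, smallest possible 0.0286), beside a cholangiocyte median of 0.73. Genes higher in c-Kit positive cells had a median of 0.13 over 220 tested in Kit-KO (camera p = 0.379 upward, exact permutation p = 0.1) and of -0.14 over 213 tested after positive infusion (camera p = 0.0941, exact permutation p = 0.371). With 1 library left out, the camera p of the second of these sets ranged from 0.00206 without negative infusion replicate 5 to 0.877 without negative infusion replicate 2. It was also under 0.05 without positive infusion replicate 3 (0.00568), and was not in the 6 other fits.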

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

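The tests of hepatocyte against stellate cell and of hepatocyte against cholangiocyte markers were chosen after the result was seen, and the others in this part were planned.

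In the knockout experiment 181 genes were higher in Kit-KO, and the 15 hepatocyte markers had a median log2 fold change of 2.10, with Alb at 996 ± 286 and 3600 ± 112 CPM and Fga at 39.3 ± 9.55 and 189 ± 35.5 CPM. Alb lies outside the naming rule and was chosen after its values were seen. A lower share of LSECs that raises every other cell type alike is argued against by the gap of 2.32 between the hepatocyte and the stellate cell medians (larger SD of members 0.23). That gap does not speak to a lower share of LSECs with unequal rises. The Kupffer cell, monocyte and neutrophil, and B cell medians were 1.55, 1.85 and 1.39. The stellate cell median was -0.22 and the sinusoidal identity median -0.62. More hepatocyte RNA in the Kit-KO libraries is a candidate source: within groups of the 14 other libraries, the 159 of 181 genes outside the hepatocyte lists that were measured correlated with the hepatocyte score at a median of 0.91, where the upper bound of 1000 matched random lists was 0.08. The labels name no gate for this experiment that would remove hepatocytes, and all 15 markers were also tested in the sorted LSECs, with none of them in another list. A change of gene expression in LSECs or hepatocytes after the deletion of Kit stays untested.

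In the sorted cells 1578 genes were lower by a log2 fold change of at least 1 in c-Kit positive cells, and the 6 cholangiocyte markers had a median of -4.25, with Spp1 at 1880 ± 160 and 82.8 ± 41.3 CPM and Epcam at 84.9 ± 9.73 and 4.13 ± 1.57 CPM. A higher share of LSECs in the c-Kit positive gate that lowers every other cell type alike is argued against by the gap of 4.98 between the hepatocyte and the cholangiocyte medians (larger SD of members 0.42). That gap does not speak to a higher share of LSECs with unequal losses. The lymphatic and stellate cell medians were -3.19 and -0.53 and the sinusoidal identity median 0.78. The hepatocyte median was 0.72 and the mast cell and progenitor median 2.08. Cholangiocyte RNA in the c-Kit negative libraries is a candidate source for part of these genes: within groups of the 14 other libraries, the 1264 measured correlated with the cholangiocyte score at a median of 0.63, where the upper bound of 1000 matched random lists was 0.15. Beyond the sort on c-Kit, no gate that would remove duct cells is named in the labels; all 6 markers were also tested in the knockout and MCD libraries, and none is in another list. Expression differences between c-Kit negative and c-Kit positive LSECs stay untested as an explanation.

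Other splits of the same samples were counted for each comparison. In the sorted cells the real split gave 1921 higher and 2624 lower genes and was 1 of 10 in each direction, with 0 genes in the highest other split; 7 of 10 splits gave as many lists, with 13 in the real and 16 in the highest other. In the knockout experiment the real split gave 181 and 7 genes and was 1 of 10 in each direction (highest other 0), and 1 of 10 for lists (16 against 15). These splits are too few for a share under 0.05, so the gene counts and the knockout lists cannot be told from chance by them. For the sorted lists, 7 of 10 splits gave as many, so chance is not excluded there either. Of the 10 sorted splits 4 part every replicate number as the real one does, and the other 3 of these gave 0 genes. In the MCD experiment the real split gave 0 higher and 0 lower genes in edgeR (highest other 0; 2537 at an unadjusted p under 0.05, and 331 higher and 453 lower in DESeq2). Any split gives at least 0, so that 35 of 35 gave as many in each direction says nothing about chance. As many lists came from 28 of 35 splits (10 in the real, 19 in the highest other), so chance is not excluded for the lists. For genes at an unadjusted p under 0.05, 1 of 35 splits gave as many (2537 against 2186). That is the smallest share these splits allow, so it goes against chance without excluding it.

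In groups of 4, 11 of 132 groups held a library far from the other 3 by Dixon's test, which at its 95% level picks 5 in 100 by chance, and all were in the MCD experiment, the only one with groups of 4. Gzma, a granzyme gene of cytotoxic lymphocytes, was at 85.57 CPM in negative infusion replicate 2 and at 18.97 to 27.95 CPM in the others of its group. Decr1, a fatty acid oxidation gene, was at 26.65 CPM in negative infusion replicate 4, with the others at 28.57 to 28.83. Negative infusion replicate 2 also lay apart in mean log2 CPM of antigen presentation genes (6.735, others 5.777 to 5.908), Notch pathway genes (4.879, others 5.285 to 5.365) and oxidative stress response genes (7.205, others 6.74 to 6.782). Positive infusion replicate 1 lay apart in hepatocyte markers (6.716, others 5.262 to 5.368), periportal hepatocyte markers (4.975, others 3.598 to 3.632) and hypoxia and glycolysis genes (6.026, others 5.881 to 5.888). Positive infusion replicate 3 lay apart in cholesterol synthesis genes (3.94, others 4.105 to 4.128) and flow response genes (6.908, others 7.097 to 7.108), and positive infusion replicate 4 in Kupffer cell and macrophage markers (3.926, others 4.391 to 4.469).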

How the results depend on the processing

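The covariates, the newer quasi-likelihood method, the use of every clock and glucocorticoid list member and the term enrichment without Kit were chosen after seeing the data, and the other alternatives were planned. In the sorted cells the counts of 1921 higher and 2624 lower genes stayed within 1.5 times under DESeq2 size factors (1924 and 2630), DESeq2 (2403 and 3028), no filter (1904 and 2588), a stricter filter (1589 and 1926), a block on the replicate number (2509 and 2957) and the newer quasi-likelihood method (1933 and 2678), and Kit kept its call. DESeq2 size factors kept 4537 of the 4545 calls. A fold minimum of 1 on the log2 scale left 263 higher and 1578 lower by its construction. Leaving out 1 library gave 1294 to 2056 higher and 2079 to 2532 lower genes, Kit at 2.86 to 3.22 and 11 to 16 lists.

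In the knockout experiment the 181 higher and 7 lower genes were 182 and 8 with DESeq2 size factors, which kept 188 of 188 calls, and 190 and 7 with the stricter filter. They were 629 and 135 in DESeq2 and 671 and 14 with the block. The lower count was 19 without a filter, 13 with the newer quasi-likelihood method and 1 with the fold minimum. With the hepatocyte score as a covariate it was 0 higher and 0 lower, and 64 of the 188 genes changed sign; the score lies at 5.109 to 5.706 in Kit-CT and 7.345 to 7.676 in Kit-KO, so it stands for the groups, and Kit was at -2.97 (adjusted p = 0.999). Kit, at -0.95 and short of the threshold, passed it at -0.96 in DESeq2, without a filter and with the block (adjusted p from 0.000343 to 0.0266), and at -0.95 with the newer method (0.0449). Leaving out 1 library gave 61 to 290 higher and 0 to 33 lower genes, Kit at -1.12 to -0.86 and 13 to 20 lists.

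In the MCD experiment the edgeR counts of 0 and 0 (2537 genes at an unadjusted p under 0.05) were also 0 and 0 with DESeq2 size factors, the stricter filter and the newer method. They were 331 and 453 in DESeq2, 4 and 5 without a filter, 8 and 31 with the block, and 34 and 133 with the monocyte and neutrophil score as a covariate, where Kit turned to 0.13 (adjusted p = 0.782). Leaving out 1 library gave 0 to 26 higher and 0 to 75 lower genes and 4 to 17 lists. DESeq2 made more false calls than edgeR in the simulated data.

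With an estimated correlation camera called 0 of its 13, 16 and 10 lists, and fry called 17, 3 and 0. In the knockout and MCD experiments the groups share 2 replicate numbers, so there the block compares 2 libraries per group with 1 residual degree of freedom, and its calls rest on less than the other fits. With it 21 lists were called in the MCD experiment. With the block the ribosomal list turned downward in the knockout (camera adjusted p of limma 0.705) and upward in the MCD experiment (0.0433). Of the 2 sets from the sorted cells, the lower one missed the threshold with an estimated correlation in the knockout (p = 0.126) and the MCD experiment (p = 0.289) and kept it in every fit that left out 1 library (3.39e-27 to 6.45e-12, and 9.33e-20 to 5.5e-05). The higher one turned downward in the knockout with the block (camera p of limma 0.804), ranged over 0.118 to 0.671 there with 1 library left out, and over 0.00206 to 0.877 in the MCD experiment. For the moves that no construction explains, the cause was not tested. Totals of 14120131 to 26575602 counts limit what genes of a few counts can show. In the knockout design edgeR recovered 3 of 67 simulated changes of 1.5-fold.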

Other observations

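The genes and terms in the first paragraphs were chosen after their values were seen, and so were all tests of clock and glucocorticoid genes in this part.

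Irf8, Xcr1, Itgax and Siglech are known from dendritic cells, a cell type for which no list was fixed or tested. In sorted c-Kit positive cells Irf8, a transcription factor gene of dendritic cell development, went from 50.3 ± 10.5 to 121.4 ± 13.7 CPM (n = 3 each, log2 fold change 1.27 ± 0.17, edgeR adjusted p = 0.00262). Xcr1, a chemokine receptor gene of cross-presenting dendritic cells, went from 3.12 ± 1.35 to 13.98 ± 3.47 CPM (2.17 ± 0.34, adjusted p = 0.00346), and Itgax, the CD11c gene, from 12.97 ± 2.13 to 27.4 ± 5.26 CPM (1.08 ± 0.18, adjusted p = 0.004). Siglech, a gene of plasmacytoid dendritic cells, was also higher (1.31 ± 0.30, adjusted p = 0.0141). In the KEGG pathways deposited with the tables, 16 of 80 genes of hematopoietic cell lineage without Kit, the gene sorted on, were among those higher by a log2 fold change of at least 1, where 1.68 were expected (adjusted p = 5.36e-10). Of the 16, 6 were MHC class II genes and 5 immunoglobulin genes. In the deposited GO processes 13 of 84 genes of chromosome segregation were, where 1.56 were expected (adjusted p = 3.5e-06, also without Kit).

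On the lower side of the sorted cells stood genes of cilia and of epithelial junctions. Foxj1, the master regulator gene of motile cilia, went from 19.3 ± 1.06 to 2.75 ± 0.214 CPM (log2 fold change -2.81 ± 0.12, edgeR adjusted p = 2.08e-05, n = 3 each), and Dnah5, an axonemal dynein gene, from 10.8 ± 2.03 to 0.435 ± 0.18 CPM (-4.63 ± 0.29, adjusted p = 5.95e-05). In the deposited annotation, 16 of 28 genes of cilium movement were among those lower by a log2 fold change of at least 1, where 3.14 were expected (adjusted p = 5.49e-06). So were 113 of 410 genes of cell adhesion (46.0 expected, adjusted p = 3.41e-17), 33 of 137 of tight junction (13.9 expected, adjusted p = 6.01e-05) and 26 of 70 of ECM-receptor interaction (7.11 expected, adjusted p = 4.35e-07). The cholangiocyte markers had a median of -4.25 in the same comparison.

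In the MCD experiment the 9 evening-phase clock genes not seen before the list was written were all positive after positive infusion, with a median of 0.77. Among them were Per3 (1.25 ± 0.23) and Dbp (1.06 ± 0.33). Their mean score differed between the groups by an exact permutation test (p = 0.0286, the smallest possible, n = 4 each). The list was written after other clock genes had shown small p in these same libraries, so this test is not independent support. Negative infusion replicate 2 alone as the cause is argued against, since the median was 1.11 without it. Another time of day at collection could bring this, but its opposite-phase genes had a median of -0.09 (exact permutation p = 0.543), with 2 of 6 positive and Arntl at -1.54 ± 0.41. The evening minus the opposite-phase score differed by 0.97 (exact permutation p = 0.0286, the smallest possible), where the evening genes alone had the same p. That difference was the first criterion, which it met; a lower opposite-phase score by its own test was asked for after this was seen, so it stays open. Glucocorticoid exposure could bring it too: 10 induced genes had a median of 0.27, 8 of them positive (exact permutation p = 0.0857). With all 14 measured, as first tested, the median was 0.45, 12 were positive and the criterion was met (exact permutation p = 0.0286). After that result Zbtb16 (2.32), Hif3a (2.45) and Klf9 (0.66), seen before the list was written, and Per1 (0.77), also a clock gene, were left out, so it stays open. An effect of the infused cells themselves stays untested, and no single clock gene passed the edgeR threshold.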
